A study of Mus musculus with 24 samples.

How the data were processed

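The libraries analysed here came from wild-type C57BL/6 mouse embryos. Open chromatin was measured by ATAC-seq in 3 libraries of Meckel's cartilage (MC) and 3 of forelimb cartilage (FL) at E14.5, and in 2 libraries of the mandibular process at E12.5. The histone mark H3K27ac was measured by CUT&Tag, in which an antibody directs a transposase to the marked chromatin, in 3 MC and 3 FL libraries at E14.5. The labels do not say whether replicates are separate animals or pools. For the 2 E12.5 libraries the titles and protocols name E12.5 mandible and ATAC-seq while the description text names another stage and assay, and the titles and protocols were followed here. Hi-C and 4C samples, among them Hi-C of mutant embryos, were not analysed here.

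Per the submitters' processing notes, reads were handled with Trim Galore, Bowtie2 and SAMtools against the mouse build mm10, and peaks were called with Genrich for ATAC-seq and SEACR for CUT&Tag; no versions or thresholds are given there. The deposited ATAC lists give for each peak the authors' peak score and a -log10 p value, and no peak has a score under 200. The deposited H3K27ac lists give for each peak the authors' total signal and highest signal, both whole numbers. Scores and signals were used only to rank peaks within a list, apart from comparisons of highest and total H3K27ac signals between lists. Each library has its own list, and the authors also gave 1 combined list per tissue, stage and assay. The authors' combined lists are pooled, so values from them have no SD, no n and no test. Read counts per library are not part of these lists, so the depth of each library is unknown and the length of each list is given in its place.

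Peaks on the autosomes and X were used. Gene positions came from the mm10 annotation of 21627 protein-coding genes. This annotation was used without strand, so promoters could not be placed at transcription start sites: a peak was called near a gene end when it lay within 1 kb of either end of a gene (2.5 kb as an alternative), and distal otherwise. Each covered base was assigned to the smallest gene span that holds it, or else to the nearest gene span within 1 Mb. For regions, the peaks of all lists of a comparison were merged, and a region was called in a list when a peak of that list overlapped it by 1 bp. Regions called in every list of one group and in no list of the other are named after the group (MC-only, FL-only, E14.5 MC-only, E12.5-only). Jaccard indices were computed on covered bases. Chance overlap was measured with 20 circular shifts of each list along its chromosomes. Shares of regions with a peak in the E12.5 lists carry 95% Wilson intervals, which cover counting error only.

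For genes, the kb covered by peaks per gene was scaled to the same total per list, and log2 values with a pseudocount of 0.5 kb were fitted with limma 3.58.1 in R 4.3.3, with statmod 1.5.0. Genes with a mean under 0.3 kb (ATAC) or 1 kb (H3K27ac) were left out. The threshold was a Benjamini-Hochberg adjusted p of 0.05. All 8 ATAC lists were in 1 fit. Gene lists written by hand were tested with limma's camera, with its preset correlation and with an estimated one. Each limma comparison tested 13 lists and was adjusted over those 13. Genes with MC-only or FL-only regions were tested with Fisher's exact test against all genes with a region that could have been called (two-sided, adjusted over 26 tests), and with a one-sided permutation test against 10000 random lists of genes with a similar number of regions. Medians of gene lists in the combined lists were ranked among 10000 random lists matched by cover in 20 bins, and the gene deserts beside Sox9 among 10000 random windows of the same size and similar cover. Other values were compared by exact permutation tests of the libraries. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

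The limma step was tested on simulated data with 100 genes planted at each of 2 log2 sizes. At a size of 3 it recovered 66% of planted genes for ATAC MC against FL (16488 genes simulated), 55% for H3K27ac (8650 genes) and 70% for E14.5 MC against E12.5 (16488 genes). At a size of 1.5 it recovered 19%, 21% and 13% in the same order. False calls were 7 of 92, 0 of 76 and 1 of 84.

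The gene lists, comparisons and alternatives were fixed before the data were examined, and so was the rule for named genes. That rule names, per limma comparison, the 10 genes of largest log2 difference each way among those past the threshold whose libraries do not overlap, or the 5 of smallest p each way where fewer than 5 pass. It adds 20 genes of cartilage, limb and jaw development whatever their values, 1 of which is not reported here, and the members with the smallest p of a list past the threshold. Named regions are those of an MC-only or FL-only class in the deserts beside Sox9 and the 5 per class whose worst rank by the authors' score within their own tissue's lists is best. Genes named outside this rule are said to have been chosen after their values were seen. The rules based on gene spans and gene ends, in place of transcription start sites, were set after the files were seen.

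Alternatives changed the pseudocount, the filter on low values, the scaling (none, or quantile normalization), the measure (number of peaks per gene), the gene domain (up to 100 kb), the authors' threshold (the same number of peaks from every list, 43205 for ATAC and 68477 for H3K27ac, or each list without the 25% of its peaks with the lowest score), the overlap (50% of a region), 500 bp bins, the samples in the fit, a replicate block, and left out each library in turn. Gene domains by the nearest gene end, the fit without E12.5 replicate 1 in the MC against FL comparison and the random genes with a similar number of regions were added after the data were seen. Motif searches were planned and not run, because no genome sequence was used here.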

Results

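The data describe the open chromatin and H3K27ac of 2 mouse cartilages at E14.5. Meckel's cartilage (MC) is the rod that shapes the developing lower jaw, and forelimb cartilage (FL) prefigures the bones of the limb. The mandibular process at E12.5, from which MC forms, was assayed for open chromatin only. ATAC-seq lists held 49090 ± 5535 peaks in MC and 57942 ± 11857 in FL (SD, n = 3 each; two-sided exact permutation p 0.4), covering 45.0 ± 1.43 and 45.7 ± 6.50 Mb. The 2 E12.5 lists held 74706 and 70042 peaks, covering 85.6 and 48.2 Mb. H3K27ac lists of single libraries held 72365 ± 3582 peaks in MC and 74527 ± 1291 in FL (SD, n = 3 each; two-sided exact permutation p 0.7). The combined H3K27ac lists held 47549 peaks over 408 Mb in MC and 39914 over 454 Mb in FL. With 3 libraries against 3, or 3 against 2, an exact p cannot go below 0.1. The depth behind the lists is unknown.

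The first comparison asks which genes carry different open chromatin in jaw and limb cartilage. Hox genes, which set position along the body and limb axes, had less ATAC peak cover in MC (limma camera, adjusted p 2.00e-13), with a median log2 difference of -1.11 and 19 of 23 genes lower. That median depends on settings, from -1.72 with a pseudocount of 0.1 kb to -0.44 with every gene of any cover (28 of 38 lower). Within that list Hoxa10 was at 0 kb in every MC library and at 3.07 ± 1.05 kb in FL, Hoxa3 at 0.163 ± 0.283 and 2.83 ± 0.552 kb, and Hoxd10 at 0 and 1.06 ± 0.197 kb (SD, n = 3). Limb patterning genes, which lay out the limb bud, were also lower in MC (adjusted p 4.93e-11), with a median of -0.88 (-0.94 to -0.46 over the settings) and 24 of 31 lower, and this list shares Hox members with the first. Among them the T-box genes Tbx18 and Tbx15, which shape the girdle and proximal skeleton, covered 2.37 ± 0.887 and 2.94 ± 0.468 kb in MC against 10.6 ± 1.02 and 8.93 ± 0.844 kb in FL. Tbx5, which starts the forelimb, covered 2.3 ± 0.855 kb in MC and 7.26 ± 0.963 kb in FL (SD, n = 3). Mandibular arch and cranial neural crest genes were higher in MC (adjusted p 0.00711), with a median of 0.28 (0.20 to 0.50 over the settings) and 28 of 40 higher. With an estimated correlation the mandibular call was lost (adjusted p 0.377) and the Hox and limb calls held (adjusted p 0.0194 and 0.0279), while the mandibular adjusted p was 0.241 with the number of peaks per gene and 0.109 without MC replicate 3. In the mandibular list Gsc, a jaw patterning gene, covered 7.87 ± 1.5 kb in MC and 1.69 ± 1.46 kb in FL. Pitx1 and Lhx6, which pattern the lower jaw, covered 6.65 ± 1.72 and 6.48 ± 0.810 kb in MC against 1.70 ± 0.935 and 2.54 ± 0.729 kb in FL (SD, n = 3).

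No single gene passed limma's threshold in this comparison. Of 16488 genes tested, 0 had an adjusted p under 0.05 and 788 had an unadjusted p under 0.05, against 824 expected by chance. The smallest adjusted p was 0.289. The error of this fit also takes in the 2 E12.5 libraries, whose lists differed from each other (Jaccard 0.198). The 788 therefore does not show that the tissues are alike. Other splits of the MC and FL libraries gave at most 387 such genes, and the number rose when E12.5 replicate 1 was left out. Libraries of the tissues did not overlap for 3068 genes (18.6%), where chance gives 10%. Adjusted over the list alone, 8 Hox genes, 6 limb patterning genes and 1 mandibular gene passed. The Hox and limb patterning counts share Hoxa10, Hoxd10, Hoxa9 and Hoxd11, so the limb patterning list added only Tbx18 and Tbx15. The 5 genes of smallest p on the MC side, none past the threshold, were Dsg3, a desmosome cadherin (2.14 ± 0.776 kb, listed at 0 in FL), Tfap2e, Fibp, Palm and Csf2. Those on the FL side were Hoxa10, Hoxa3, Hsd11b1, a steroid enzyme (1.93 ± 0.618 kb, listed at 0 in MC), Impg2, a retinal matrix protein (2.98 ± 0.520 kb, listed at 0 in MC), and Mtnr1b. Fitted on MC and FL alone, Impg2 (log2 difference -2.65, limma adjusted p 0.0312) and Hoxa10 (-2.66, adjusted p 0.0464) passed.

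Genes of cartilage, limb and jaw named in advance are given next, whatever their values. Col2a1, the main collagen of cartilage, covered 13.5 ± 3.97 kb in MC and 7.24 ± 0.668 kb in FL, without overlap (SD, n = 3; limma adjusted p 1). Sox9, which drives cartilage formation, covered 11.6 ± 1.96 kb in MC and 14.53 ± 3.02 kb in FL, a difference within the spread. Its partners Sox5 and Sox6 covered 18.6 ± 2.97 and 18.2 ± 1.22 kb in MC against 26.3 ± 0.835 and 25.4 ± 1.94 kb in FL. Acan and Matn1, which encode matrix proteins, covered 6.95 ± 0.886 and 6.78 ± 1.28 kb in MC and 5.67 ± 1.41 and 3.92 ± 2.05 kb in FL. Alx4, a craniofacial regulator, covered 11.4 ± 3.94 kb in MC and 3.88 ± 0.920 kb in FL without overlap, and Shox2, of the proximal limb, 3.8 ± 0.655 and 8.40 ± 2.85 kb. Runx2 (12.4 ± 3.73 and 13.3 ± 0.968 kb), Six2, Barx1, Dlx5, Ihh, Hoxa13 and Hoxd13 overlapped between the tissues, while Dlx6 (7.90 ± 1.52 and 3.81 ± 0.131 kb) and Hand2 (10.4 ± 1.59 and 17.3 ± 2.60 kb) did not. The cartilage list had an adjusted p of 0.179 in camera (0.0268 without FL replicate 1 and 0.0376 without MC replicate 2) and the hypertrophy and osteoblast list 0.179. The lists of Pierre Robin sequence genes (0.232), tendon (0.240), endothelium (0.601), blood (0.621), epithelium (0.681), neuron and Schwann cell (0.778), reference genes (0.778) and skeletal muscle (0.854) were not called either. For muscle and for neuron and Schwann cell the median and the mean had opposite signs.

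**Figure D1:**
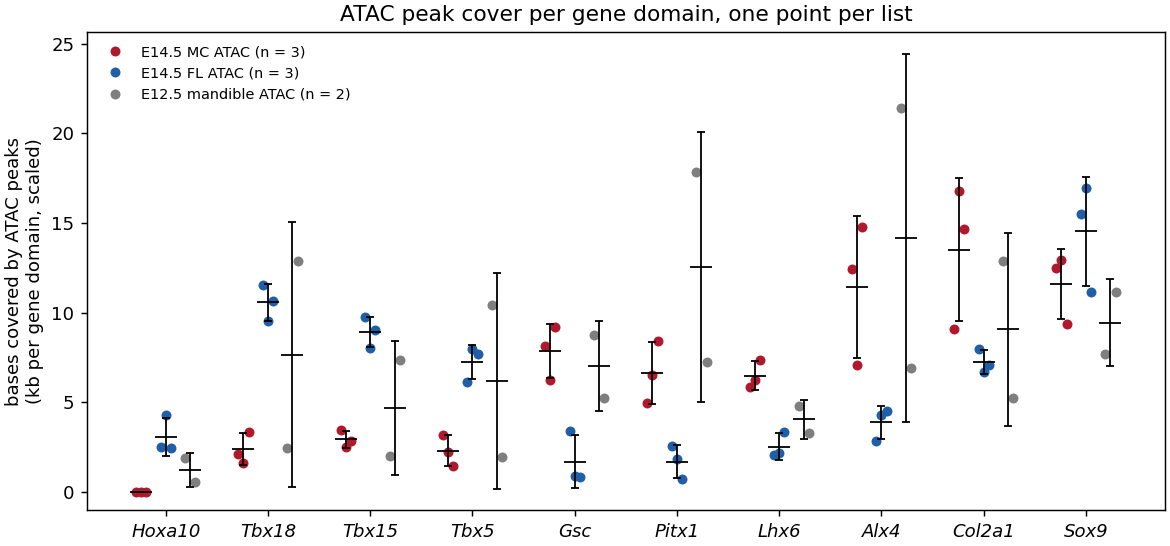
ATAC peak cover (kb per gene domain, scaled to the same total; vertical axis) of 10 genes in each library, with 1 point per library, a dash for the mean and bars for the SD. Tbx5 lies at 2.3 kb in MC and 7.26 kb in FL, and Gsc at 7.87 and 1.69 kb; the E12.5 points (n = 2) lie far apart for several genes.

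The second comparison asks where in the genome the tissues differ. Of 113676 ATAC regions, 586 were MC-only, 2564 were FL-only and 20047 were called in every list. FL-only regions fell in the domains of 16 of 28 limb patterning genes, among them Tbx5, Tbx15, Shox2, Shh and Hoxa10 (57.1% against 13.2% of all genes; odds ratio 8.87; Fisher's exact test, two-sided, adjusted p 1.25e-06). Random genes with a similar number of regions reached 29.9% on average (one-sided permutation, adjusted p 0.0052). For Hox genes the values were 5 of 13 genes (38.5%; Fisher's exact adjusted p 0.0976, or 0.00284 and 0.0108 without FL replicates 1 and 3; permutation adjusted p 0.0052, against 4.2% of matched genes). MC-only regions fell in the domains of 5 of 25 cartilage genes, Col2a1, Fgfr3, Sox5, Sox6 and Wwp2 (20.0% against 4.10%; odds ratio 5.90; Fisher's exact adjusted p 0.0397). Genes with a similar number of regions reached 10.0% (permutation adjusted p 0.510), so that call did not hold against them, nor without MC replicate 3 (Fisher's exact adjusted p 0.136). Mandibular genes with MC-only regions were 5 of 37, Alx4, Dlx6, Gsc, Lhx8 and Pax9 (13.5%; Fisher's exact adjusted p 0.0976, or 0.00645, 0.00649 and 0.00045 without MC replicate 1, FL replicate 1 and FL replicate 2). Against the 7.97% of matched genes they did not stand out (permutation adjusted p 0.536). FL-only regions fell in the domains of 9 of 34 mandibular genes (26.5%; Fisher's exact adjusted p 0.135; permutation adjusted p 0.571). Tendon genes with FL-only regions were 6 of 15 (Fisher's exact adjusted p 0.0773, or 0.00284 and 0.0316 without FL replicates 1 and 2). Gsc, Ext2, Elfn2 and Zfhx3 had the most MC-only regions, 3 each, and Adgrl3, Atp6ap1l and Mctp2 the most FL-only regions, 7 each. These genes were chosen after their values were seen.

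The best-ranked FL-only regions (mm10) lay at 9:14841251-14843038 near Mre11a, a DNA repair gene, at 17:77199398-77200994 nearest to Crim1, at 9:92717417-92719647 by Plod2, which modifies collagen, at 10:53434308-53435784 by Cep85l and at 19:30450555-30451869 by Dkk1, a Wnt inhibitor. The best-ranked MC-only regions lay at 12:104634597-104635977 by Dicer1, of microRNA processing, at 2:93689617-93691609 by Ext2, which builds heparan sulfate, at 12:8055959-8057136 by Apob, at 18:26955038-26956412 nearest to Celf4 and inside Elmo1 at 13:20397508-20399017. Of MC-only regions 10.4% lay near a gene end, against 3.51% of FL-only regions and 54.4% of regions in every list. With the same number of peaks from every list there were 790 MC-only and 1596 FL-only regions. Peak lists were on average more alike within than between tissues (mean Jaccard 0.419 and 0.389; one-sided exact permutation p 0.1, the smallest possible). The ranges of single pairs overlapped (0.363 to 0.470 within and 0.330 to 0.443 between). MC replicate 3 was closest to MC replicate 2 (0.470), but closer to each FL list (0.411 to 0.443) than to MC replicate 1 (0.377). MC lists had 29.6 ± 2.93% of peaks near a gene end and FL lists 25.4 ± 3.77% (SD, n = 3; two-sided exact permutation p 0.2).

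**Figure D2:**
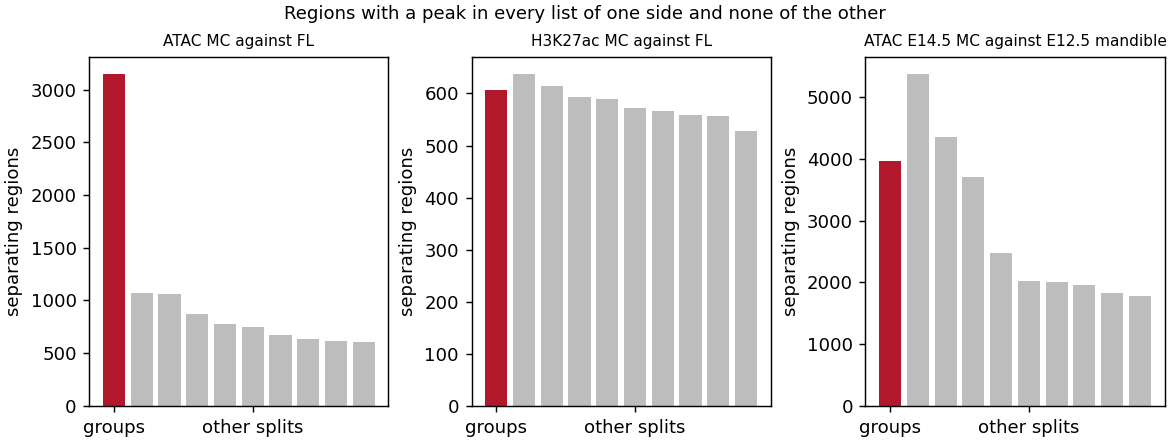
Number of regions with a peak in every list of one side and none of the other (vertical axis), for the real groups (red) and the other splits of the same libraries (grey), in the 3 comparisons. For ATAC MC against FL the groups give 3150 and the highest other split 1067; for H3K27ac they give 606 and 638, and for E14.5 MC against E12.5 3967 and 5375.

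The third comparison asks which genes carry H3K27ac in each cartilage, from the authors' pooled lists. The kb are given as listed. The smallest total signal of a listed peak was 16925 in MC and 25799 in FL. A gene listed at 0 in FL, here and below, may therefore hold signal under the lowest that list shows. Log2 ratios, and counts of genes higher in a tissue, use cover scaled to the same total per tissue. Dlx6, which sets lower jaw identity, had 33.8 kb of H3K27ac in MC and was listed at 0 in FL, and Msx1, of the facial mesenchyme, had 53.3 and 4.80 kb. Tbx5 had 99.9 kb in FL and was listed at 0 in MC, and Tbx15 had 87.6 kb in FL and 4.04 kb in MC. Meis2, with 146 kb, and Irx1, with 32.0 kb, in MC and Sall3, with 35.3 kb, in FL were listed at 0 in the other tissue; Meis2, Irx1, Msx1, Sall3 and Tbx15 were chosen after their values were seen. Gsc (56.9 kb in MC and 47.4 kb in FL) and Pitx1 (22.7 and 19.4 kb), which had more ATAC cover in MC, differed less. Hand2 had 29.4 kb in MC and 10.0 kb in FL, Six2 58.1 and 30.1 kb, Runx2 167 and 132 kb, and Shox2 16.3 and 38.9 kb. Among matrix genes Col2a1 (46.7 and 48.8 kb) and Acan (93.4 and 95.1 kb) were close to equal while Matn1 had 61.2 kb in MC and 150 kb in FL. After scaling the log2 ratios of Col2a1 and Acan were slightly above 0 (0.09 and 0.13). Both lay near the middle of the 15802 genes ranked (percentiles 51.5 and 55.2), so neither leaned to MC relative to other genes. Sox9 had 159 kb in MC and 119 kb in FL, Sox5 506 and 397 kb, and Sox6 303 and 297 kb.

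By gene list, mandibular genes had a median log2 ratio of 0.61, with the highest percentile of all lists (100 among 10000 random lists of matched genes; 27 of 32 genes higher in MC). Hox genes had a median of -3.62 (percentile 0; 10 of 10 higher in FL) and limb patterning genes -0.31 (percentile 0.06; 17 of 29 higher in FL). Of the 22 limb patterning genes that are not Hox genes, 12 were higher in MC (median 0.15), among them Meis2 and Meis1, which mark the proximal limb bud. Of all 15802 genes ranked, most were higher in MC, as a log2 ratio of 0.018 lay at percentile 45.0. The 12 of 22 is therefore no excess over all genes. Neuron and Schwann cell genes had a median of 3.08 (percentile 99.97; 6 of 9 higher in MC), with Stmn2, Elavl3 and Tubb3 listed at 0 in FL, at 8.91, 8.11 and 4.56 kb in MC, 3 genes chosen after their values were seen, as was Meis1. Hypertrophy and osteoblast genes had a median of 0.39 (percentile 99.38). Percentiles of the other lists were 94.05 for cartilage, 93.47 for Pierre Robin sequence genes, 90.9 for reference genes, 63.79 for blood, 27.71 for skeletal muscle, 9.57 for epithelium, 6.23 for endothelium and 4.17 for tendon. In the combined ATAC lists the percentiles were 99.99 for mandibular genes and 0 for both Hox and limb patterning genes. Hypertrophy and osteoblast genes were at 98.27 and cartilage genes at 95.06. Other lists ranked otherwise than for H3K27ac: neuron and Schwann cell genes were at 4.89 (69.02 with domains up to 100 kb) and Pierre Robin sequence genes at 3.175. The rest were at 85.41 (blood), 44.05 (reference genes), 35.89 (muscle), 24.78 (tendon), 19.78 (epithelium) and 4.13 (endothelium). Of the combined H3K27ac peaks, 23.4% in MC and 21.6% in FL had no peak of the other tissue.

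**Figure D3:**
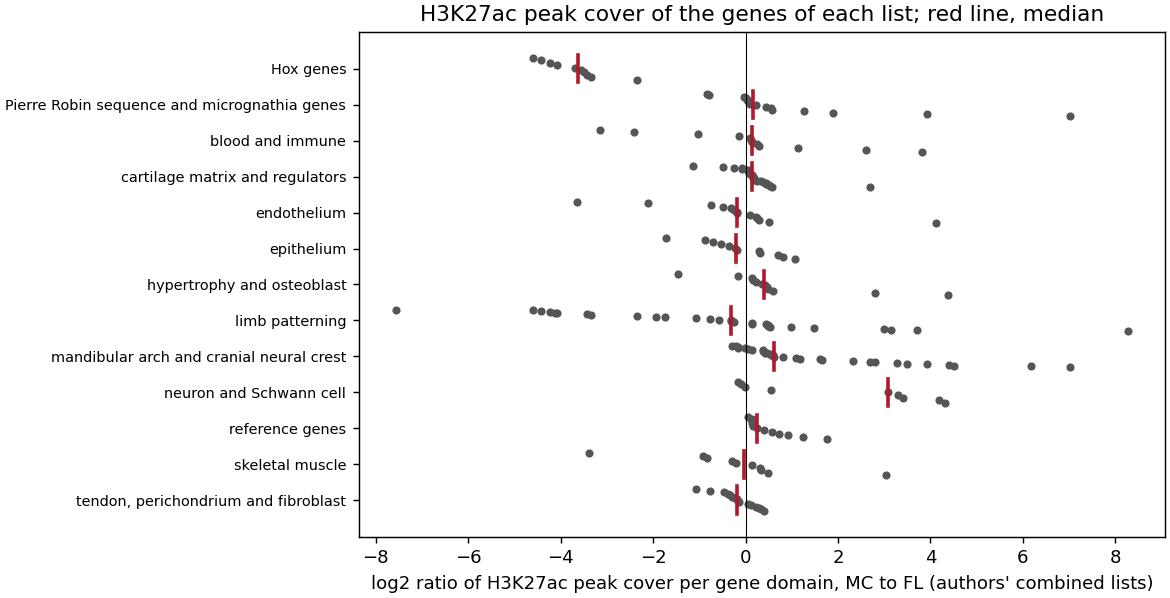
Log2 ratio of H3K27ac peak cover scaled to the same total, MC to FL (horizontal axis), of each measured gene of the 13 lists in the authors' combined lists, with 1 point per gene and a red line for the median. The median lies at 0.61 for mandibular genes and at -3.62 for Hox genes.

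Distal open regions were then set against the combined H3K27ac lists. Of 525 distal MC-only ATAC regions, 69.9% overlapped MC H3K27ac and 64.0% FL H3K27ac. Of 2474 distal FL-only regions, 39.1% overlapped MC and 43.8% FL H3K27ac. Regions with the mark in MC alone numbered 63 and in FL alone 32 among the MC-only, and 211 and 326 among the FL-only. Of distal regions in every list, 79.5% overlapped MC and 73.0% FL H3K27ac. There 997 had the mark in MC alone and 403 in FL alone. More regions marked in MC alone than in FL alone is therefore not particular to the MC-only regions.

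H3K27ac was also compared in the lists of single libraries. Peaks of these lists met the combined H3K27ac lists 0.571 to 0.759 times as often as shifted peaks, so the 2 kinds of list are not taken to measure the same thing. Pax1, of the axial skeleton, covered 20.8 ± 5.37 kb in MC and 9.20 ± 2.13 kb in FL (SD, n = 3), and the skin gene S100a7l2 2.93 ± 1.05 and 10.97 ± 1.59 kb (limma adjusted p 0.121 each). Further genes of small p were Gsdmc, Zfp770, Arhgap15 and Etnk1 on the MC side and Pate5, Nap1l3, Skint6 and Htr2c on the FL side, none past the threshold. Sox9 covered 15.3 ± 7.10 kb in MC and 12.4 ± 3.43 kb in FL, a difference within the spread, and the other genes named in advance and reported here overlapped too where measured. Tbx5 (5.32 ± 3.51 kb in MC and 3.41 ± 1.38 kb in FL; limma adjusted p 0.892) and Dlx6 (3.36 ± 1.3 and 5.35 ± 3.4 kb; adjusted p 0.866; SD, n = 3) leaned opposite to the combined lists. Limma called 0 of 8650 genes, with 665 at an unadjusted p under 0.05 against 432.5 expected. The 0 depends on settings: without MC replicate 3 it called 2 genes higher in MC and 42 in FL, and with a pseudocount of 2 kb 1 and 7. Libraries did not overlap for 1065 genes (12.3%), where chance gives 10%. Of 13 gene lists none was called, the lowest adjusted p being 0.151 for endothelium, and skeletal muscle reached 0.00795 without FL replicate 3. For cartilage, Hox, Pierre Robin sequence and blood genes the median and mean had opposite signs, and for mandibular genes the median and the test. Of 381868 regions, 271 were MC-only, 335 FL-only and 4 in every list. The best-ranked lay by Kcnj3, Spaca7 and Aadat, in Ptprd and nearest to Dsel (MC-only) and in Sec14l3 and by Ccser1, Onecut1, Taf4 and Thrb (FL-only). Within-tissue Jaccard indices averaged 0.0158 and between-tissue ones 0.0153 (one-sided exact permutation p 0.1). Near a gene end lay 4.00 ± 0.220% of peaks in MC and 3.97 ± 0.223% in FL lists (SD, n = 3; two-sided exact permutation p 1), against 29.3% and 31.3% in the combined lists. MC-only ATAC regions held an H3K27ac peak of a single library in 3.36% (MC lists) and 3.87% (FL lists) of cases (two-sided exact permutation p 0.6).

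The study's stated interest is in distal enhancers of Sox9 in MC, so the gene deserts on both sides of Sox9 on chromosome 11 were compared. Between Kcnj2 and Sox9 (11:111076826-112782209, 1.71 Mb) the combined H3K27ac lists held 27 peaks over 157 kb in MC, 15 of them without an FL peak, and 16 peaks over 102 kb in FL, 3 of them without an MC peak. The lowest total signal in the combined lists was 16925 in MC and 25799 in FL. Weak FL peaks may thus be missing from this count. ATAC peaks there numbered 8.67 ± 2.52 in MC and 19.3 ± 2.52 in FL (SD, n = 3; two-sided exact permutation p 0.1), or 1.74 ± 0.325 and 3.41 ± 0.641 per 10000 peaks of a list (exact permutation p 0.1). With the same number of ATAC peaks from every list the difference was -6.33 peaks (two-sided exact permutation p 0.2). FL-only ATAC regions lay at 11:111961099-111962147 and 11:112697591-112698640, at 820.6 and 84.1 kb from the end of Sox9 that faces Kcnj2, and there was no MC-only region. Between Sox9 and Slc39a11 (11:112787758-113244850, 0.46 Mb) ATAC peaks numbered 15.0 ± 3.00 in MC and 23.0 ± 11.5 in FL (SD, n = 3; two-sided exact permutation p 0.4), with no region of either class. H3K27ac there came to 18 peaks over 209 kb in MC and 13 over 215 kb in FL.

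The last comparison sets E14.5 MC against the E12.5 mandible. Since the E12.5 samples are whole mandibular processes and the E14.5 samples dissected cartilage, stage and tissue composition cannot be told apart. Sall4, a regulator of early progenitors, covered 0.351 ± 0.344 kb in E14.5 MC (SD, n = 3) and 2.60 ± 0.992 kb at E12.5 (SD, n = 2), and Glp1r, which encodes a hormone receptor, 0.636 ± 0.712 and 11.8 ± 2.63 kb. Neither passed limma's threshold, and both belong to the 5 genes of smallest p on the E12.5 side with Tmem130, Cfap74 and Dnah8; on the MC side these were Fmo6, H60c, Ugt1a10, Il5 and Oit3. Gene lists lower in E14.5 MC by camera were Hox (adjusted p 8.00e-06; median -0.46; 20 of 23 lower), limb patterning (0.000194; -0.36; 19 of 31 lower), epithelium (0.000222; -0.53; 11 of 14 lower), skeletal muscle (0.0112; -0.39; 12 of 16 lower) and blood (0.0227; -0.34; 6 of 11 lower). None of these calls held with an estimated correlation (adjusted p 0.0908, 0.0962, 0.0908, 0.0962 and 0.209), and each was lost when 1 E12.5 library was left out. Without E12.5 replicate 1 the adjusted p was 0.105 for Hox and 0.868 for muscle and blood, and without replicate 2 it was 0.146 for limb patterning and 0.0849 for epithelium. In the epithelium list Krt14, a keratin, covered 0.147 ± 0.254 kb at E14.5 and 1.36 ± 0.494 kb at E12.5 (SD, n = 3 and 2). The median of all genes was 0.24, or -0.12 without scaling and 0.04 after quantile normalization, and the 5 list medians stayed negative in all 3. Pierre Robin sequence genes had a median of 0.62 (15 of 17 higher; adjusted p 0.0833) and cartilage genes 0.44 (adjusted p 0.0833, or 0.00875 without E12.5 replicate 1 and 0.0411 without MC replicate 2). Reference genes (0.0643), neuron and Schwann cell (0.293), tendon (0.293), mandibular (0.358), endothelium (0.443) and hypertrophy genes (0.990) were not called. For hypertrophy, mandibular, endothelium and neuron and Schwann cell genes the test pointed down although the median was above 0, and for endothelium and neuron and Schwann cell genes the mean was below 0. Sox9 covered 11.6 ± 1.96 kb in E14.5 MC and 9.45 ± 2.44 kb at E12.5 (SD, n = 3 and 2), a difference within the spread. Of the genes named in advance and reported here only Acan had no overlap between the stages (6.95 ± 0.886 and 5.12 ± 0.984 kb, limma adjusted p 0.707).

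Limma called 0 of 16488 genes between the stages, with 1012 at an unadjusted p under 0.05 against 824 expected and a smallest adjusted p of 0.553. Without E12.5 replicate 2, with E12.5 replicate 1 alone, it called 3823 genes higher in E14.5 MC and 1050 higher at E12.5. Libraries did not overlap for 3192 genes (19.4%), where chance gives 20% for 3 libraries against 2. Of the ATAC regions, 1418 were E14.5 MC-only and 2549 E12.5-only, with 2.82% and 10.9% near a gene end. The larger side turned with the same number of peaks from every list (2127 and 539) and with 50% of a region covered (1978 and 1719). The best-ranked E12.5-only regions lay in Glp1r (17:30903651-30914786), by Rassf9, in Selenov, in Ptprf and by Tyw3, and the best-ranked E14.5 MC-only by Npepl1, by Tg, in Anxa1, by Slc44a3 and by Pcdh1. The E12.5 lists differed from each other: replicate 1 had Jaccard indices of 0.197 to 0.244 with the MC lists and 0.198 with replicate 2, which had 0.317 to 0.420 with the MC lists. Of MC-only regions of the first comparison, 23.5% (95% Wilson interval 20.3 to 27.2) had a peak in both E12.5 lists, against 3.67% (3.01 to 4.47) of FL-only regions and 79.1% of regions in every list. In E12.5 replicate 1 the shares were 47.3% of MC-only and 6.71% of FL-only regions, and in replicate 2 46.9% and 34.8%.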

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

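Chosen only after the data were seen were the gene domains by nearest gene end, the MC against FL fit without E12.5 replicate 1, the limb patterning genes of the combined H3K27ac lists without Hox genes and the test against random genes with a similar number of regions. Unless a cause is named below, the cause was not tested. The Hox and limb patterning lists, lower in MC than FL, kept their direction and their call under each alternative in which camera was run, with adjusted p ranging from 8.97e-17 to 0.0194 and from 8.32e-12 to 0.0279. These were the estimated correlation, the number of peaks, domains up to 100 kb, the nearest gene end, the replicate block and left-out libraries. Under the other settings camera was not run. The size of the difference moved more. The Hox median (-1.11) was -1.72 with a pseudocount of 0.1 kb, -0.45 with one of 2 kb and -0.44 with every gene of any cover (28 of 38 lower), and the limb patterning median (-0.88) was -0.46 with a pseudocount of 2 kb and -0.55 with domains up to 100 kb. The mandibular median (0.28) was 0.20 with a pseudocount of 2 kb and 0.50 without MC replicate 2. Between the stages the blood median (-0.34) was at 0.0043 with a pseudocount of 0.1 kb, and 17 of 31 limb patterning genes were higher in E14.5 MC without E12.5 replicate 2. The similarity of peak lists and the ATAC peaks between Kcnj2 and Sox9 and between Sox9 and Slc39a11 kept their direction, in 6 of 6 and 16 of 16 alternative values. The share of peaks near a gene end kept its direction for ATAC in both comparisons. For H3K27ac the MC minus FL difference was 0.031 percentage points at 1 kb and -0.0067 at 2.5 kb, both within the spread. Since an exact p cannot go below 0.1 here, these results had no call to keep or lose. Between Kcnj2 and Sox9 the difference of -10.7 peaks ranged from -11.8 to -9.33 with 1 library left out, and with the same number of peaks from every list it was -6.33 and the tissues overlapped. Between Sox9 and Slc39a11 the difference of -8 ranged from -13.5 without FL replicate 3 to -2 without FL replicate 2.

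Counts of regions moved with the rules. With the same number of peaks from every list there were 1596 FL-only ATAC regions, 539 E12.5-only against 2127 E14.5 MC-only regions and, among distal FL-only regions, 714 with FL H3K27ac and 206 with FL and no MC H3K27ac. With 500 bp bins there were 1547 MC-only ATAC regions, 110 MC-only and 131 FL-only H3K27ac regions, 3510 E14.5 MC-only and 4264 E12.5-only regions. With 50% of a region covered, 75 MC-only and 98 FL-only H3K27ac regions were counted, and 7.34% of MC-only and 1.83% of FL-only ATAC regions had a peak in both E12.5 lists. Without the lowest 25% of each list there were 145 MC-only and 185 FL-only H3K27ac regions and 1671 E12.5-only regions. By the authors' combined lists there were 5534 MC-only and 14255 FL-only ATAC regions, 11146 and 8639 H3K27ac regions, and 7912 E14.5 MC-only and 25884 E12.5-only regions, since a single list per tissue needs no agreement of replicates. The larger side turned between the stages with the same number of peaks and with 50% of a region covered (1978 E14.5 MC-only and 1719 E12.5-only regions, against 1418 and 2549 as reported) and, for H3K27ac, by the combined lists (271 MC-only and 335 FL-only as reported).

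Leaving out 1 library asks fewer lists to agree, so these counts rise by construction. MC-only ATAC regions ranged from 725 to 1735, with 1507, 1735 and 1361 without MC replicates 1, 2 and 3 and 1276 without FL replicate 2. FL-only ATAC regions ranged from 3151 to 5915, with 5364 and 5915 without FL replicates 1 and 3 and 3961 without MC replicate 3. MC-only H3K27ac regions ranged from 308 to 3261, with 3261, 3148 and 3101 without MC replicates 1, 2 and 3, and FL-only from 367 to 3472, with 3472, 3367 and 3414 without FL replicates 1, 2 and 3. E14.5 MC-only regions ranged from 2151 to 6046, with 2552, 2730 and 2183 without MC replicates 1, 2 and 3 and 2151 and 6046 without E12.5 replicates 1 and 2. E12.5-only regions ranged from 3190 to 37041, with 24776 and 37041 without E12.5 replicates 1 and 2. Distal MC-only regions with MC H3K27ac ranged from 454 to 961 and those without FL H3K27ac from 80 to 186, past 1.5 times the value without MC replicate 1 (956 and 151), 2 (961 and 186) or 3 (853 and 115) or FL replicate 2 (795 and 136). Distal FL-only regions with FL H3K27ac ranged from 1381 to 2586 and those without MC H3K27ac from 390 to 720, past 1.5 times the value without FL replicate 1 (2166 and 617) or 3 (2586 and 720), and the first also without MC replicate 3 (1774). The share with a peak in both E12.5 lists ranged from 16.3 to 47.3% of MC-only and from 3.45 to 34.8% of FL-only regions, the highest values coming from a single E12.5 list (without replicate 2 for MC-only, without replicate 1 for FL-only). With replicate 2 as the only E12.5 list the shares were 46.9 and 34.8%, and with replicate 1 47.3 and 6.71%. FL-only regions came to 5.97 and 8.99% without MC replicates 2 and 3.

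Gene lists past the threshold lost their call as follows. With an estimated correlation the adjusted p was 0.377 for mandibular genes (MC against FL), and between the stages 0.0962 for limb patterning, 0.0908 for Hox, 0.0962 for muscle, 0.209 for blood and 0.0908 for epithelium. With the number of peaks per gene it was 0.241 for mandibular genes, and between the stages 0.0687 for muscle and 0.0762 for blood. With a replicate block it was 0.0575 for blood between the stages. Against random genes with a similar number of regions, cartilage genes with MC-only regions had 0.510. Leaving out 1 library gave 0.00045 to 0.109 for mandibular genes (highest without MC replicate 3), 0.00262 to 0.136 for cartilage genes with MC-only regions (highest without MC replicate 3), and between the stages 4.13e-06 to 0.105 for Hox, 5.42e-05 to 0.146 for limb patterning, 2.30e-05 to 0.0849 for epithelium, 0.00187 to 0.868 for muscle and 0.00627 to 0.868 for blood. Hox was lost without E12.5 replicate 1, limb patterning and epithelium without E12.5 replicate 2, muscle without either (0.0849 without replicate 2), and blood without either (0.0804 without replicate 2) or without MC replicate 3 (0.0814).

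Counts of genes past limma's threshold were 0 in each comparison, with 788, 665 and 1012 genes at an unadjusted p under 0.05. For ATAC MC against FL the count was 2 on the FL side with only the 2 groups compared, and 0 to 1 with 1 library left out (1 without E12.5 replicate 1). For H3K27ac it was 1 MC and 7 FL genes with a pseudocount of 2 kb and 3 MC and 11 FL genes with a replicate block. Leaving out 1 H3K27ac library gave 0 to 2 MC and 0 to 42 FL genes: 2 and 42 without MC replicate 3, 4 FL genes without MC replicate 1, and 1 gene each way without FL replicate 1. Between the stages it was 0 to 3823 E14.5 MC genes and 0 to 1050 E12.5 genes, both highest without E12.5 replicate 2, with 7831 at an unadjusted p under 0.05. In each fit with 1 E12.5 library the lone sample is assumed to vary like the other groups. The libraries were taken to share only a number, since the labels give no pairing and no pair of MC and FL libraries of the same number correlated over 0.1 once each group's mean was removed (0.0644, 0.0702 and 0.0672 for ATAC, -0.0127, -0.0217 and 0.0330 for H3K27ac). As a hint from the data, every ATAC library of these tissues correlated best with its own number in the other, while for H3K27ac this held for replicate 3 and not for replicates 1 and 2; E14.5 MC and E12.5 libraries of the same number were at -0.0875 and -0.280. Apart from the H3K27ac counts and blood between the stages, the replicate block changed no call of a list or count of genes past the threshold.

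Lists that were not called changed direction under these settings, none of them past the threshold. With the number of peaks per gene the adjusted p was 0.551 for muscle (ATAC MC against FL), 0.975 for limb patterning (H3K27ac) and 0.687 for hypertrophy genes (between the stages). With domains up to 100 kb it was 0.776 for neuron and Schwann cell genes (ATAC MC against FL), 0.967 for limb patterning and for neuron and Schwann cell genes (H3K27ac) and 0.976 for hypertrophy genes (between the stages). With a replicate block it was 0.922 for cartilage genes (H3K27ac). With 1 library left out, ranges for lists that changed direction in ATAC MC against FL were 0.519 to 0.962 for muscle, 0.504 to 0.972 for neuron and Schwann cell, 0.198 to 0.972 for blood and 0.133 to 0.972 for epithelium. In H3K27ac they were 0.789 to 0.990 for cartilage, 0.841 to 0.990 for hypertrophy, 0.462 to 0.990 for limb patterning, 0.697 to 0.990 for Hox, 0.307 to 0.990 for blood, 0.752 to 0.990 for tendon, 0.849 to 0.990 for Pierre Robin sequence genes and 0.654 to 0.990 for neuron and Schwann cell. Between the stages they were 0.402 to 0.942 for hypertrophy, 0.151 to 0.868 for tendon and 0.0828 to 0.942 for mandibular genes.

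Named genes that changed sign had small differences or wide spreads. In ATAC MC against FL, Ihh (reported log2 difference -0.02) was at 0.071 with the number of peaks and at 0.28 with the same number of peaks from every list, and Runx2 (-0.14) at 0.10 by nearest gene end. In H3K27ac, Barx1 (-0.03) was at 0.0083 with a pseudocount of 2 kb and at 0.00065 without scaling, and Sox5 (-0.03) at 0.016 without scaling and at 0.0072 after quantile normalization. With domains up to 100 kb Shox2 (-0.16) was at 0.17 and Matn1 (-0.04) at 0.29. Between the stages without scaling, Sox9 (0.29) was at -0.20, Six2 (0.13) at -0.35 and Acan (0.41) at -0.069, where the median of all genes was -0.12 in place of 0.24. Alx4 (-0.15) was at 0.10 after quantile normalization and at 0.16 with the same number of peaks from every list, and Hoxd13 (-0.38) at 0.12 with the number of peaks.

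With 1 library left out, genes that changed sign ranged in ATAC MC against FL from -0.78 to 0.73 (Ihh), -0.34 to 0.084 (Runx2) and -0.11 to 0.21 (Six2). In H3K27ac they ranged from -1.03 to 0.18 (Acan), -1.04 to 0.041 (Alx4), -0.48 to 0.26 (Barx1), -0.19 to 0.084 (Matn1), -0.52 to 0.050 (Shox2), -0.57 to 0.15 (Six2), -0.18 to 0.077 (Sox5), -0.093 to 0.52 (Sox6), -0.10 to 0.53 (Sox9) and -0.030 to 1.06 (Tbx5). Between the stages they ranged from -0.94 to 0.63 (Alx4), -0.42 to 2.06 (Dlx6), -0.63 to 1.86 (Hand2), -1.18 to 0.49 (Hoxd13), -2.49 to 0.41 (Matn1), -0.34 to 1.79 (Shox2), -0.29 to 0.56 (Six2), -0.35 to 2.14 (Sox5), -0.092 to 1.68 (Sox6) and -2.01 to 0.15 (Tbx5). Between the stages the sign changed without E12.5 replicate 1 for these genes except Hoxd13 (without replicate 2), and for Alx4 also without MC replicate 2. In the other direction, Hox genes with FL-only regions passed against random genes with a similar number of regions (0.0052). Named genes passed the threshold in 15 cases under other settings and in 28 cases with 1 library left out, and lists not called passed in 15 cases with 1 library left out. By camera these were cartilage in ATAC MC against FL (0.0268 without FL replicate 1, 0.0376 without MC replicate 2) and between the stages (0.00875 without E12.5 replicate 1, 0.0411 without MC replicate 2), and skeletal muscle in H3K27ac (0.00795 without FL replicate 3). By MC-only regions they were mandibular genes (0.00645, 0.00649 and 0.00045 without MC replicate 1, FL replicate 1 and FL replicate 2) and blood (0.0196 without FL replicate 3). By FL-only regions they were Hox (0.00284 and 0.0108 without FL replicates 1 and 3), Pierre Robin sequence genes (0.0113 and 0.0271 without FL replicates 1 and 3) and tendon (0.00284 and 0.0316 without FL replicates 1 and 2). Of all alternative values, 340 of 392 for lists not called and 1424 of 1516 for named genes kept their direction and their side of the threshold. The planned motif searches were not run. The depth of the libraries is unknown, so how far it limits the number of peaks and of called genes is unknown too.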

Other observations

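Tests chosen only after the result was seen were the genome build and signal scale of the single-library H3K27ac lists, the longer FL lists and single FL library as causes of the FL-only excess, the equal-number test between Kcnj2 and Sox9, and the other splits for regions and genes; the remaining tests were fixed before.

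Limb identity was visible without the replicate test on single genes, and jaw identity less firmly. The combined H3K27ac lists hold Dlx6 (33.8 kb) and Lhx6 (9.50 kb) in MC alone and Tbx5 (99.9 kb) and Hoxa10 (12.2 kb) in FL alone, and the single-library ATAC lists give Gsc, Pitx1 and Lhx6 more cover in MC. In the combined H3K27ac lists, however, Gsc (56.9 kb in MC and 47.4 kb in FL) and Pitx1 (22.7 and 19.4 kb) differed less. The lowest total signal in those lists was 16925 in MC and 25799 in FL, so weak FL peaks may be missing. The mandibular list (adjusted p 0.00711) was not called with an estimated correlation (0.377), with the number of peaks per gene (0.241) or without MC replicate 3 (0.109), and 1 other split of the libraries gave a smaller unadjusted p (0.00127 against 0.00164). The single-library H3K27ac lists do not show this: Tbx5 (5.32 ± 3.51 kb in MC and 3.41 ± 1.38 kb in FL) and Dlx6 (3.36 ± 1.3 and 5.35 ± 3.4 kb) overlapped and leaned the other way (SD, n = 3; limma adjusted p 0.892 and 0.866). Limb genes were not uniformly higher in FL: by scaled cover in the combined H3K27ac lists 12 of 29, and 12 of the 22 that are not Hox genes, were higher in MC. Neither count is an excess, since most of the 15802 genes ranked were higher in MC (a log2 ratio of 0.018 lay at percentile 45.0). As listed, Meis2, among the 12 limb genes higher in MC, was at 146 kb in MC and at 0 in FL, and Meis1 at 176 and 24.2 kb in MC and FL. Ptch1, also among them, was slightly lower in MC as listed (91.4 and 92.1 kb). These genes were chosen after their values were seen. Of the MC-only open regions 23.5% were open in both E12.5 mandible lists, against 3.67% of FL-only regions, and with E12.5 replicate 2 alone the shares were 46.9 and 34.8%.

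The single-library H3K27ac lists overlapped each other little more than shifted lists: the Jaccard index of 2 lists of a tissue was at most 1.58 times that of shifted lists, against 39.9 to 50.5 times for ATAC. Weak calls let in by a loose threshold would leave the strongest peaks in place, but the 1000 strongest peaks of each list met the combined list (4.5 to 8.5% of them) at most 0.455 times as often as shifted peaks. The total signal of a peak reached at most 3459 in these lists (FL replicate 2), but was at least 16925 in the combined MC list and 25799 in the combined FL list. These ranges do not meet. The strongest listed peaks may therefore not be strong places, and the test cannot decide about weak calls. Coordinates of another genome build would still let the 6 lists overlap each other, which the ratio of 1.58 argues against. The highest signal in the combined lists (50 in MC and 49 in FL) was at least 1.69 times the sum of the highest signals of the 3 lists (29 in each tissue). Since these lists avoid the combined peaks, their signal at the strongest places is not known, so the same reads on the same scale behind both kinds of list remain open. Whether other reads or settings lie behind these lists stays open: 91.5% of the strongest combined FL peaks held a peak of 1 of the 3 lists, but shifted FL lists gave 94.7 to 98.3%, so the bound of 90% set for this test was wrong, since shifted lists pass it too, and no biological explanation was tested.

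Between Kcnj2 and Sox9, H3K27ac covered more in the combined MC list while ATAC peaks were more numerous in FL. The MC excess of H3K27ac lay at percentile 96.63 of random windows of the same size, between the 2 bounds set beforehand, so an excess found in many windows remains open. The combined ATAC lists held 4 peaks over 2.83 kb in MC and 10 over 7.90 kb in FL. This FL excess of combined cover lay at percentile 7.1, so one as large was found in many windows and it does not stand out. The number of peaks per library was not ranked among windows. With the same number of peaks from every list the difference was -6.33 peaks with an overlap of the tissues, while the peaks per 10000 of a list did not overlap, so longer FL lists also remain open. A difference between the tissues in the use of this desert is a biological explanation that stays open and untested.

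FL-only ATAC regions outnumbered MC-only ones (2564 and 586). With the same number of peaks from every list, 1596 FL-only and 790 MC-only regions were left, so a smaller FL excess remained. The test set FL-only regions against the highest side of any other split, 628. Both classes exceeded it, so that test cannot tell an FL excess from a difference between the tissues. Longer FL lists as the whole cause were therefore not settled by it. A single FL library as the whole cause remains open. With 2 MC lists against 2 FL lists, FL-only regions were at least 1.34 times the MC-only regions in all 9 sets, but with the same number of peaks from every list FL-only regions were more in 8 of 9, with a ratio of 0.973 without FL replicate 2 and MC replicate 1. A difference between the tissues stays open and untested, and so do cell mixture and library quality.

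Other splits of the same libraries number 10 with the real one, too few for a share under 0.05. As many regions as the real groups came from 1 split for ATAC MC against FL (3150, highest other 1067), from 3 for H3K27ac (606, highest other 638) and from 3 between the stages (3967, highest other 5375). Genes past the threshold were 0 for the real groups, so all 10 splits gave as many, with a highest other of 0 for ATAC MC against FL, 0 for H3K27ac and 44 between the stages. At an unadjusted p under 0.05 limma gave 788 genes for ATAC MC against FL (highest other 387) and 665 for H3K27ac (highest other 600). The split with 44 genes, and 3443 at an unadjusted p under 0.05 against 1012 for the real groups, points to a structure of the samples other than stage. For the lists in ATAC MC against FL, an unadjusted camera p as small came from 1 split for Hox, 1 for limb patterning and 2 for mandibular genes (0.00164, smallest other 0.00127). Adjusted over the lists of a split, p was 2.00e-13, 4.93e-11 and 0.00711 for the real groups, and the smallest in another split was 1.98e-05, 0.0017 and 0.0165.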
